A study of Homo sapiens with 22 samples.

How the data were processed

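K562 cells, a human line from a chronic myeloid leukaemia, stably carried the bacterial biotin ligase BirA and, in part of the samples, a FLAG- and biotin-tagged form of the transcription factor WT1, per the labels' protocols. Both tagged constructs held the 17 amino acid insert of WT1, and they differed in whether the amino acids lysine, threonine and serine (KTS) stood between the last pair of zinc fingers. Chromatin was crosslinked with 1% formaldehyde for 10 minutes and sheared by sonication. Biotinylated WT1 was captured on 3 mg of streptavidin beads, and H3K4me3, a histone mark of active promoters, was immunoprecipitated from the same lysates with an antibody. Of 22 libraries in the labels, 13 had a peak list. The 9 input libraries had none among the files used here and were not analysed here.

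The authors deposited 1 peak list per library. Per the submitters' processing notes, the tools were Bowtie2 2.2.7 and MACS2 2.1.1.20160226 and the genome build was hg19. The control used for peak calling, the read filters and the calling threshold are not given in the sources used here. Each deposited list gave chromosome, start, end and a whole-number score per peak, with no summit, fold enrichment or read count. The lowest score was 50 in all lists from WT1 −KTS cells and 13 in all others. MACS2 writes such a score as 10 times −log10 of a q or p value. On that reading, taken from the values and not from a label, the lists from WT1 −KTS cells were called at 1e-05 and the others at about 0.05. The score is the authors' own value per peak and served only to rank or filter peaks within a list. A score of at least 50, the planned stricter setting, puts all lists at the same lowest score. Whether every list's score comes from the same kind of value is unknown, so equal scores need not mean equal stringency. Names of the lists from WT1 −KTS cells contain the word pooled, and what was pooled is not stated. The read depth per library is unknown from the lists, so the number of peaks cannot be set against sequencing effort.

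Peaks on chromosomes 1 to 22, X and Y were used. Peaks overlapped when they shared at least 1 bp. A consensus region of an isoform was a merged region called in at least 2 replicates that overlapped no peak of any untagged library, and H3K4me3 consensus regions were merged regions called in at least 2 replicates. Chance overlap came from 1000 random rotations of the peaks along each chromosome (200 for consensus regions at H3K4me3, 20 for pairs of libraries), with a one-sided p whose smallest value is 0.000999 for 1000. The length of a chromosome was taken as the largest peak end in any list, so gaps in the assembly were included and no list of unreliable regions was removed. Because peaks cluster in gene-rich stretches, a stricter chance level, chosen after the data were seen, moved each chromosome's peaks by 20 to 100 kb only. Numbers of peaks were compared on the log10 scale with two-sided exact permutation tests. Intervals are exact Clopper-Pearson 95% intervals, which are binomial, over peaks, which are not independent, and cover counting error only. Equal lists were the 3245 best-scoring peaks of each WT1 library, the length of the shortest, and the 27341 best of each H3K4me3 library. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used. On simulated data with 30% of peaks planted on a target list, 29.97% were recovered, and 4% of 200 unrelated pairs of lists passed a p of 0.05. The simulated peaks were spread at random over the chromosomes and tested with whole-chromosome rotations only. They therefore do not check the p-values of clustered peaks or the moves of 20 to 100 kb. Overlaps and consensus regions matched those of bedtools 2.31.1.

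The groups, the tests, the alternative settings and the rule for naming regions were fixed before the data were examined. Planned counts of peaks at transcription start sites and in exons, introns and promoters, the 10 fixed gene lists and the search for the WT1 motif were not run, because an annotation or sequence of hg19 was not used here. By the same rule, 3 regions in each set were named by coordinates, 1-based on hg19, in place of genes. They had the best worst rank over the libraries that called the region, so a named +KTS region can be absent from 1 replicate. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.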

Results

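Binding of the WT1 −KTS and +KTS isoforms in K562 cells was measured by streptavidin capture of biotinylated protein in 2 and 3 libraries, with 3 libraries from cells that carried the ligase but no tagged protein as background. H3K4me3 was measured in 3 libraries of WT1 −KTS cells and 2 of WT1 +KTS cells.

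Cells with tagged WT1 gave far longer peak lists than cells without it. WT1 −KTS replicates 1 and 2 had 154732 and 3245 peaks. WT1 +KTS replicates 1, 2 and 3 had 543203, 373510 and 35455. The untagged libraries had 743, 101 and 311. The geometric mean of the 5 tagged libraries was 285 times that of the 3 untagged ones, a log10 difference of 2.46, with an exact two-sided permutation p of 0.0357, the smallest that 56 splits allow. With a score of at least 50 in every list the ratio was 991, with the same exact p of 0.0357. Against untagged, the ratio was 78.4 for −KTS (exact p = 0.2) and 675 for +KTS (exact p = 0.1), each the smallest p the design allows. With a score of at least 50 these ratios were 344 and 2009, with the same exact p-values. For −KTS the log10 difference of 1.89 became 1.06 without −KTS replicate 1 and 2.73 without −KTS replicate 2, and for +KTS that of 2.83 became 2.60 without +KTS replicate 1 and 3.20 without +KTS replicate 3. Leaving out any 1 of the 8 libraries kept the log10 difference between 2.23 and 2.81, with an exact p of 0.0571 or 0.0952.

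**Figure D1:**
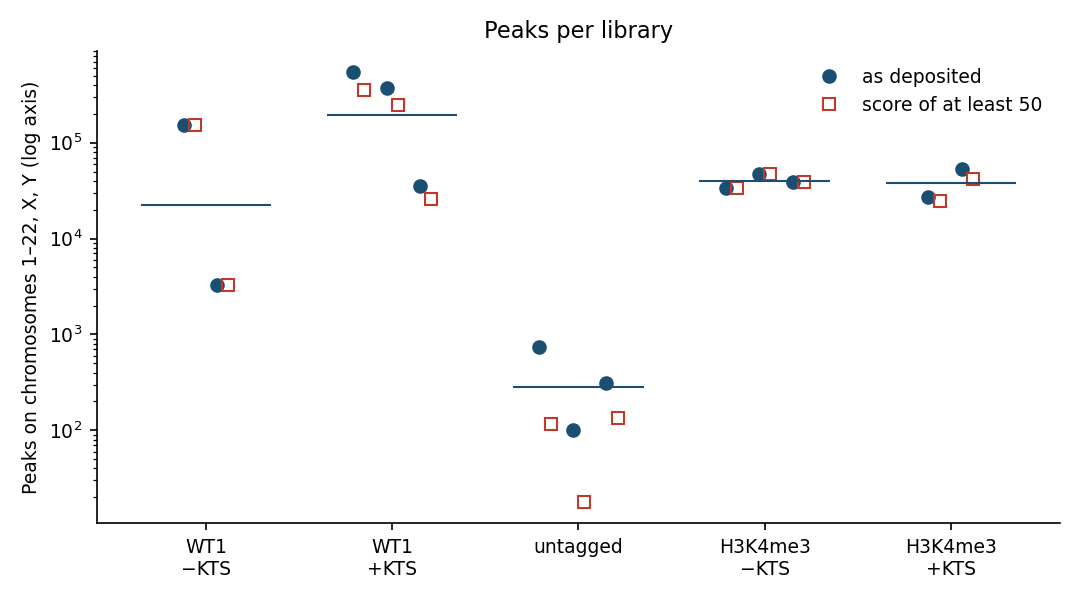
Number of peaks per library on a log axis, as deposited (filled points) and with a score of at least 50 (open squares); horizontal lines mark the geometric mean of the deposited lists of a group. The untagged libraries lie between 101 and 743 peaks, below every tagged library.

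WT1 +KTS cells gave longer lists than WT1 −KTS cells on average, but the libraries of each isoform overlapped in range. The geometric mean was 8.61 times higher in +KTS (exact two-sided permutation p = 0.4) and 5.85 times higher with a score of at least 50 (exact p = 0.4), where 0.2 is the smallest p for 2 libraries against 3. Single libraries set this ratio, since the log10 difference of 0.94 became 0.10 without −KTS replicate 2, 1.77 without −KTS replicate 1, 0.71 without +KTS replicate 1 and 1.30 without +KTS replicate 3. Within an isoform, the longest list held 47.7 times as many peaks as the shortest in −KTS and 15.3 times in +KTS. Peaks were narrower in −KTS, with median widths of 133 and 152 bp, than in +KTS, with 301, 252 and 222 bp (exact p = 0.2, the smallest possible). The narrowest peak of a list differed in the same direction, at 103 and 109 bp in −KTS and 170 bp or more in +KTS. Among untagged replicates 1, 2 and 3, narrowest peaks of 123, 91 and 193 bp went with medians of 139, 108 and 213 bp. Whether the difference in median width comes from the isoform or from the calling of each list was not tested. The lists covered 25.0 and 0.552 Mb in −KTS and 205.6, 119.7 and 8.59 Mb in +KTS. Codes in the names of the lists were shared by the +KTS and untagged libraries of the same number. Within the 3 codes the +KTS list was 731, 3698 and 114 times as long, or 3053, 13618 and 195 times with a score of at least 50. No −KTS list carried such a code, so isoform and a possible batch cannot be told apart.

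The untagged capture gave few peaks, and many of them lay in the longer WT1 lists. The untagged lists merged into 1150 regions, of which 5 were found in at least 2 untagged libraries and 0 in all 3. Because they are so few, they could meet only a small share of WT1 peaks, and overlapped 0.185% and 0.0308% of −KTS peaks and 0.105%, 0.0723% and 0.451% of +KTS peaks. The shares were 12.9, 4.67, 3.53 and 25.3 times those of random rotations in −KTS replicate 1 and +KTS replicates 1, 2 and 3, each with a one-sided permutation p of 0.000999, the smallest possible. For −KTS replicate 2 the ratio was 2.25 from 1 peak (permutation p = 0.357). Without untagged replicate 3 the shares were 0.0924% and 0% in −KTS and 0.0681%, 0.0319% and 0.0536% in +KTS. Without untagged replicate 1 they were 0.107% in −KTS replicate 1 and 0.0440% and 0.0469% in +KTS replicates 1 and 2. With a score of at least 50 in every list the shares were 0.0653% and 0.0308% in −KTS and 0.0416%, 0.0330% and 0.275% in +KTS. These were 17.6, 9.52, 7.10, 6.20 and 61.0 times random rotations, where 9.52 came from 1 peak. Seen from the untagged side with the deposited lists, 16.2%, 21.8% and 44.7% of the peaks of untagged replicates 1, 2 and 3 lay in −KTS replicate 1, and 0%, 0% and 0.322% in −KTS replicate 2. In +KTS replicate 1 they were 45.1%, 35.6% and 65.6%, in replicate 2 12.8%, 23.8% and 48.6%, and in replicate 3 0.673%, 13.9% and 45.3%. Against moves of 20 to 100 kb, these were 3.53, 2.60 and 2.78 times, 1.66, 2.61 and 2.98 times, and 0.704, 13.2 and 19.6 times in the +KTS libraries. On chromosome 22, 26 of 30, 3 of 3 and 37 of 37 untagged peaks lay between 17 and 24 Mb.

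**Figure D2:**
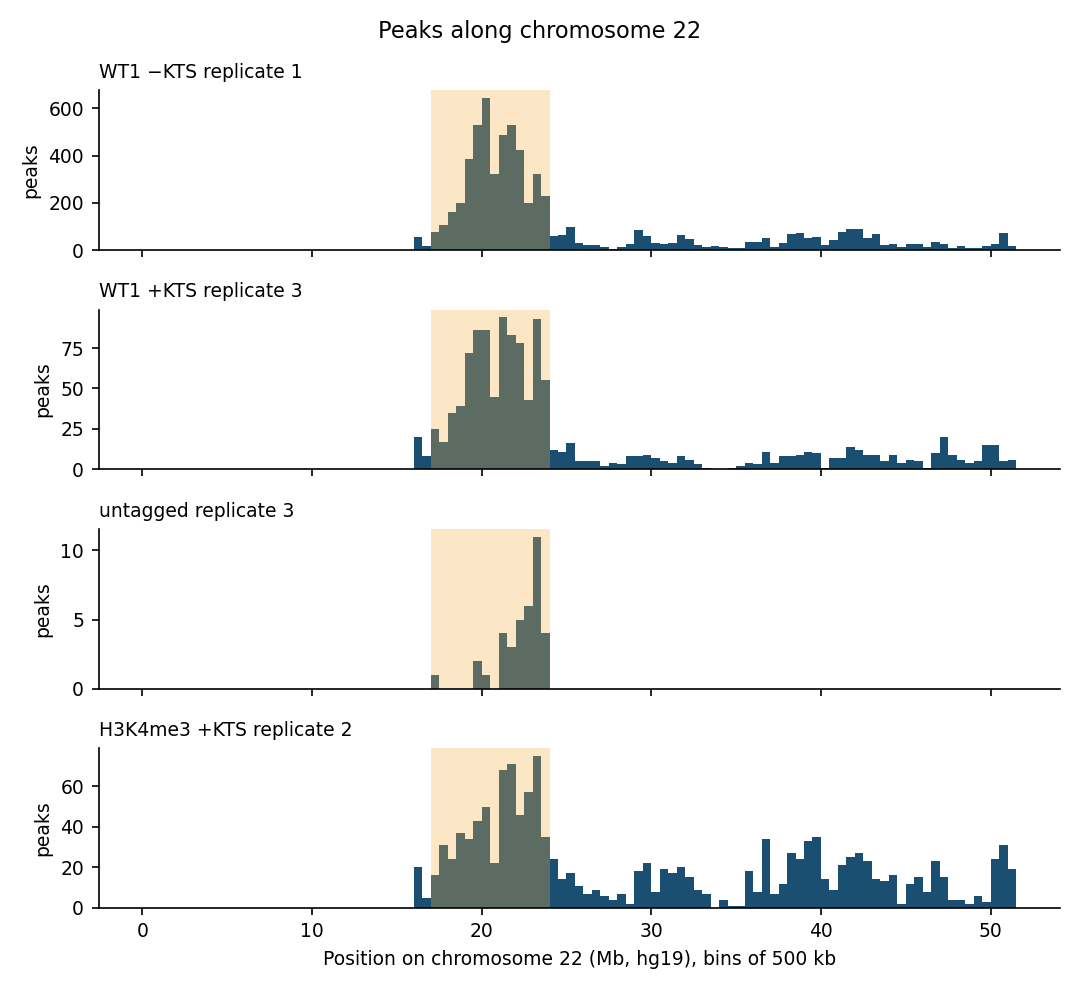
Number of peaks along chromosome 22 in bins of 500 kb for WT1 −KTS replicate 1, WT1 +KTS replicate 3, untagged replicate 3 and H3K4me3 +KTS replicate 2; the stretch from 17 to 24 Mb is shaded. All 37 peaks of untagged replicate 3 lie in it.

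The +KTS lists gave more recurrent regions than the −KTS lists as deposited, but the lists differ in length and a region needed 2 of 3 +KTS libraries against 2 of 2 −KTS libraries. There were 2022 −KTS consensus regions covering 0.517 Mb and 285002 +KTS regions covering 145.8 Mb, of which 21055 were called in all 3 replicates. At a score of at least 50 the +KTS number was 162606, and with equal lists there were 801 −KTS and 1550 +KTS regions. The direction turned when equal lists were held to every replicate, with 801 −KTS and 285 +KTS regions. That rule asks for 3 of 3 +KTS against 2 of 2 −KTS libraries and so is stricter for +KTS. Neither rule treats the isoforms alike, so the turn is not evidence of fewer recurrent +KTS regions. The +KTS number rested on replicates 1 and 2, since it was 22362 without replicate 1 and 29801 without replicate 2. Among the 3245 best peaks of each library, 24.7% of −KTS replicate 1 lay in −KTS replicate 2, which was 422 times chance. The same peaks lay in +KTS replicates 1, 2 and 3 at 20.5%, 11.2% and 5.33%, or 23.1, 19.3 and 40.7 times chance. For −KTS replicate 2 these shares were 1.94%, 1.76% and 0.493%, against 25.1% in −KTS replicate 1. Among +KTS libraries, 42.3% of replicate 1 lay in replicate 2 and 15.0% in replicate 3.

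**Figure D3:**
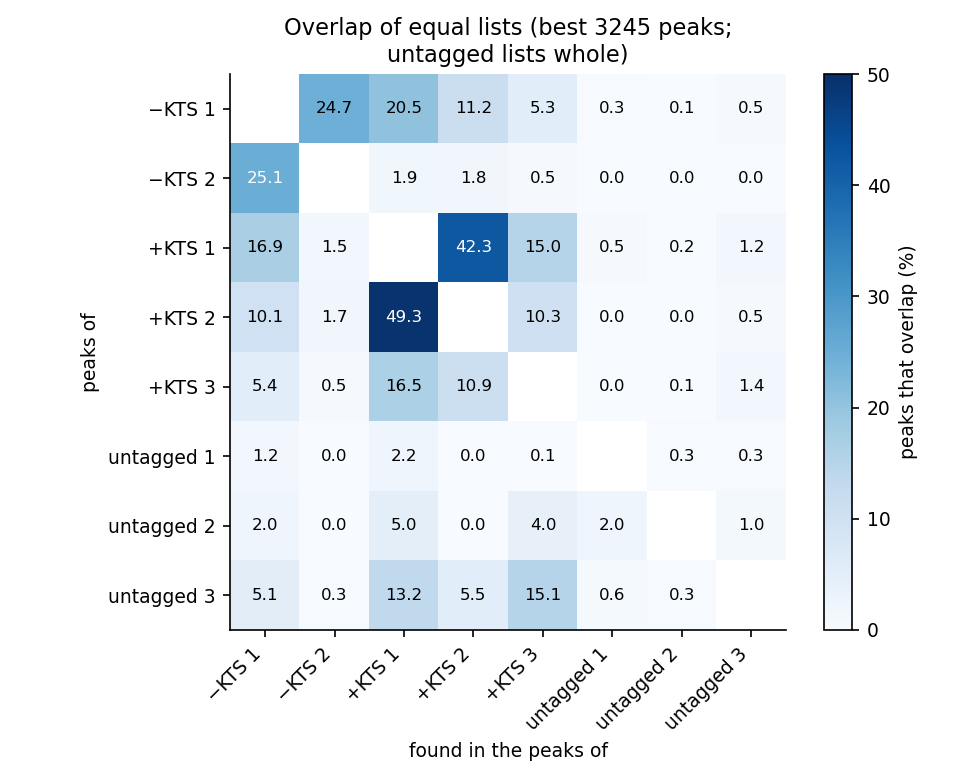
Share of the peaks of the row library that overlap a peak of the column library, in percent, with each WT1 list reduced to its 3245 best peaks and the untagged lists whole. Overlap is highest between +KTS replicates 1 and 2, at 42.3% and 49.3%, and lies near 25% between both −KTS libraries.

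Of the 2022 −KTS regions, 951 (47.0%, interval 44.8% to 49.2%) overlapped a +KTS region and 1071 did not. Random rotations gave 9.44%, so the overlap was 4.98 times chance (one-sided permutation p = 0.000999, the smallest possible), and moves of 20 to 100 kb gave 22.1%, a ratio of 2.13. At a score of at least 50 the overlap was 577 regions (28.5%, against 5.75% by rotation and 14.0% by moves of 20 to 100 kb). It was 20 of 801 regions with equal lists (2.50%, against 0.173% and 1.42%, or 1.76 times the latter). It fell to 50 regions without +KTS replicate 1 and to 61 without +KTS replicate 2. The best-ranked −KTS regions outside +KTS regions lay on chromosome 7 at 16626175 to 16626540, chromosome 20 at 62959558 to 62959794 and chromosome 19 at 45256619 to 45257015. Each of these 3 overlapped H3K4me3 in 1 of 3 libraries of −KTS cells and 2 of 2 of +KTS cells. The best-ranked +KTS regions outside −KTS regions lay on chromosome 22 at 23052150 to 23053025, chromosome 21 at 10204084 to 10205235 and chromosome 5 at 17597233 to 17599636, and the last of these was at H3K4me3. Those of both isoforms lay on chromosome 1 at 143283043 to 143283428 and on chromosome 22 at 22711339 to 22712861 and 22901020 to 22902210. Of these, the second overlapped H3K4me3 in 0 of 3 libraries of −KTS cells, and each of the 3 in both libraries of +KTS cells. The region at 22901020 to 22902210 was not called in +KTS replicate 3. Neither were the +KTS regions outside −KTS regions on chromosomes 22 and 21. The named regions of chromosome 22 lie in the stretch from 17 to 24 Mb where untagged peaks were dense. None of the named regions, on any chromosome, was checked against a list of unreliable regions, so some may be artefacts.

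WT1 peaks lay at H3K4me3 regions of the same cells more often than chance in both isoforms. At regions found in both cells, +KTS replicate 3 exceeded random rotations but not moves of 20 to 100 kb. In −KTS replicates 1 and 2 the shares were 4.49% (interval 4.39% to 4.60%) and 47.3% (45.5% to 49.0%). In +KTS replicates 1, 2 and 3 they were 3.13% (3.08% to 3.17%), 7.15% (7.07% to 7.23%) and 2.45% (2.30% to 2.62%). These were 3.77, 38.6, 2.50, 5.76 and 2.27 times random rotations and 1.90, 18.4, 1.37, 2.93 and 1.33 times moves of 20 to 100 kb, all with a one-sided permutation p of 0.000999, the smallest possible. Without H3K4me3 −KTS replicate 2 or 3 the share was 2.61% or 2.88% in −KTS replicate 1 and 27.9% or 28.7% in −KTS replicate 2. At the regions found in both cells, +KTS replicate 3 had 1.34% against 1.02% by rotation, or 1.31 times (one-sided permutation p = 0.000999, the smallest possible). Against moves of 20 to 100 kb, a level chosen after the data were seen, its share was 0.770 times the 1.74% of the moves (permutation p = 1.0), while the other WT1 libraries had 1.28 times or more. Untagged replicates 1, 2 and 3 had 0 of 743, 0 of 101 and 2 of 311 peaks at these regions, where rotations gave 0.880%, 0.795% and 1.00%. The median distance from a peak to the nearest H3K4me3 region was 25.1 and 0.031 kb in −KTS and 32.8, 27.5 and 37.7 kb in +KTS.

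Whether the isoforms differ in this share cannot be decided with 2 libraries against 3. The mean was 25.9% ± 30.2 (SD, n = 2) in −KTS and 4.24% ± 2.54 (SD, n = 3) in +KTS (exact two-sided permutation p = 0.4). Without −KTS replicate 2 the difference of 21.6 percentage points became 0.250, and without −KTS replicate 1 it became 43.0. It became 11.0 without H3K4me3 −KTS replicate 2 and 11.5 without replicate 3. With equal lists the shares were 17.7% and 47.3% in −KTS and 7.83%, 15.5% and 3.51% in +KTS, so that both −KTS libraries exceeded every +KTS library (exact p = 0.2, the smallest that 10 splits allow).

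**Figure D4:**
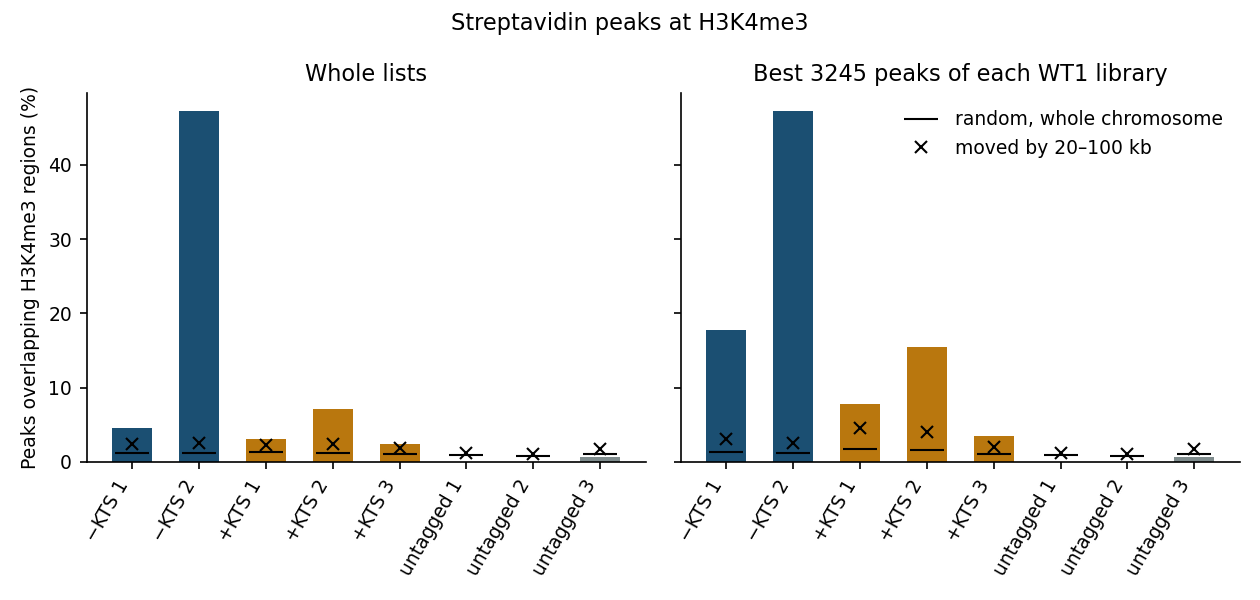
Share of streptavidin peaks that overlap H3K4me3 consensus regions, in percent, for whole lists (left) and the 3245 best peaks of each WT1 library (right); bars are single libraries, dashes the mean of random rotations and crosses that of moves by 20 to 100 kb. WT1 −KTS replicate 2 stands at 47.3%, and with equal lists both −KTS libraries exceed every +KTS library.

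Recurrent −KTS regions lay at H3K4me3 in 969 of 2022 cases (47.9%, interval 45.7% to 50.1%) and +KTS regions in 14293 of 285002 (5.02%, 4.94% to 5.10%). Random rotations gave 1.35% and 1.38% (permutation p = 0.00498 each, the smallest that 200 rotations allow). Moves of 20 to 100 kb gave 3.01% and 2.64%, so the ratios fell from 35.6 to 15.9 in −KTS and from 3.63 to 1.90 in +KTS (permutation p = 0.00498 each, the smallest possible). A −KTS region needed a peak of both −KTS libraries, so the short list of replicate 2 bounds these regions. Peaks of replicate 2 lay at H3K4me3 in 45.8% of cases inside −KTS regions and 49.7% outside. For replicate 1 these were 46.3% and 3.94%. The −KTS share thus follows replicate 2 and is not separate evidence from both libraries. With equal lists the shares of consensus regions were 41.4% (38.0% to 44.9%) in −KTS and 11.9% (10.3% to 13.6%) in +KTS. The −KTS share was 59.4% for regions without a +KTS region and 35.0% for those with one. Among +KTS regions it was 43.5% for the 952 that met a −KTS region and 4.89% for the rest. The −KTS share was 30.2% without H3K4me3 −KTS replicate 2 and 30.9% without replicate 3, and the +KTS share was 2.78% without streptavidin +KTS replicate 2. Seen from the mark, 3.59% of H3K4me3 regions in −KTS cells held a −KTS region and 57.7% of those in +KTS cells held a +KTS region, or 33.0% at a score of at least 50. The region sets covered 0.517 Mb in −KTS and 145.8 Mb in +KTS, and no chance level was computed for these shares. At H3K4me3 regions found in all 5 libraries, moves of 20 to 100 kb alone gave 19.4% and 0.517% for −KTS replicates 1 and 2. For +KTS replicates 1, 2 and 3 they gave 50.8%, 36.1% and 4.30%, so the contrast follows list length at least in part.

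H3K4me3 was found largely at the same places in cells of both isoforms. There were 33511, 47165 and 38716 peaks in −KTS cells and 27341 and 53149 in +KTS cells, and the geometric mean in +KTS was 0.967 times that in −KTS (exact two-sided permutation p = 1.0). The covered length averaged 16.7 Mb ± 6.91 (SD, n = 3) in −KTS and 26.2 Mb ± 5.74 (SD, n = 2) in +KTS cells (exact p = 0.4). Of 29582 consensus regions in −KTS cells, 81.0% were found in +KTS cells, and of 21612 in +KTS cells, 87.6% were found in −KTS cells. The latter was 52.1% without −KTS replicate 2 and 58.0% without replicate 3. Of 72310 regions in any library, 11693 were in all 5 and 43374 in 1 only, of which 24103 were in +KTS replicate 2. With a score of at least 50, 33808 were in 1 only and 14454 of them in +KTS replicate 2, and with equal lists 16161 and 4296.

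Few H3K4me3 regions followed the isoform in every library. There were 221 regions in all −KTS and no +KTS libraries and 1489 in both +KTS and no −KTS libraries, or 279 and 1009 at a score of at least 50. The first number was 1127 without −KTS replicate 1, 1640 without −KTS replicate 3, 453 without +KTS replicate 1 and 710 without +KTS replicate 2. The second was 25726 without +KTS replicate 1 and 3805 without +KTS replicate 2. The best-ranked regions of the first set lay on chromosome 5 at 22212319 to 22213808, chromosome 12 at 121810358 to 121812530 and chromosome 2 at 48133805 to 48134382. Those of the second set lay on chromosome 1 at 220891575 to 220893284, chromosome 9 at 136152855 to 136153338 and chromosome 20 at 25731275 to 25731726.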

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

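All tests of unplaced sequences were chosen after the lists were seen. The comparisons above left out sequences without a place on a chromosome. Of these, the contig gl000220, which carries ribosomal RNA genes, held 61 of the 3333 peaks of WT1 −KTS replicate 2 (1.83%, interval 1.40% to 2.34%), against 2 of the 1179 peaks of the untagged libraries together (0.170%; Fisher's exact test, one-sided, adjusted p = 0.000362 over 295 tests). This p treats the peaks of 1 library as independent, so it covers counting error only. It was the only 1 of 59 sequences and 5 tagged libraries to pass. WT1 −KTS replicate 1 had 66 and the WT1 +KTS libraries 43, 49 and 23 peaks on the same contig, smaller shares of longer lists than in the untagged libraries, and whether the share of replicate 2 comes from its short list was not tested. The H3K4me3 libraries had 39, 29 and 10 peaks there in −KTS cells and 39 and 41 in +KTS cells.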

How the results depend on the processing

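Settings and left-out libraries changed many sizes and some directions. As deposited, 81.0% of H3K4me3 −KTS and 87.6% of +KTS regions were found in the other cells. Which share was higher turned with equal lists and with calls in every replicate, which asks for 3 of 3 −KTS but 2 of 2 +KTS libraries. With a score of at least 50, the median number of peaks was 245129 in +KTS and 115 in untagged, +KTS had 162606 consensus regions (4.36% at H3K4me3), 577 −KTS and 576 +KTS regions overlapped, and 78.8% of H3K4me3 −KTS and 90.3% of +KTS regions were found in the other cells. Requiring 0.5 of the shorter peak gave 32.9% of −KTS and 4.65% of +KTS regions at H3K4me3, and 77.8% and 86.7% for the H3K4me3 regions. Equal lists gave 801 −KTS and 1550 +KTS regions (41.4% and 11.9% at H3K4me3), of which 20 and 19 overlapped, H3K4me3 shares of 88.3% and 78.9%, and 117 H3K4me3 regions in every −KTS and no +KTS library. Calls in every replicate gave 21055 +KTS regions (10121 with a score of at least 50, an added setting), 61 −KTS and 59 +KTS regions that overlapped, 14486 H3K4me3 −KTS regions, and 94.6% and 57.1% found in the other cells. Calls in any replicate gave 155637 −KTS and 609217 +KTS regions. At H3K4me3 regions found in both cells the shares of consensus regions were 45.6% and 4.30%. Leaving out 1 library at a time gave these ranges. The median number of peaks was 3245 to 154732 in −KTS, 204482.5 to 458356.5 in +KTS and 206 to 527 in untagged. Tagged against untagged stayed at 2.23 to 2.81 log10, with an exact p no longer under 0.05 because fewer splits remain. Consensus regions in +KTS were 22362 to 285181, with 50 to 952 −KTS and 49 to 953 +KTS regions that overlapped, and 2.78% to 5.18% of +KTS and 30.2% to 47.9% of −KTS regions lay at H3K4me3. H3K4me3 −KTS regions were 14016 to 28168, of which 84.7% to 94.4% were found in +KTS cells, and 52.1% to 86.7% the other way. H3K4me3 regions in every −KTS and no +KTS library were 239 to 1640, and 1548 to 25726 in the other direction. The log10 ratio of the number of H3K4me3 peaks, −0.01 as reported, was −0.16 to 0.13, and it turned to 0.13 without +KTS replicate 1 and to 0.02 without −KTS replicate 2. With the number as a replicate block, +KTS against untagged stayed at 2.83 log10 (exact sign-flip p = 0.25, the smallest possible for 3 pairs). Correlations of chromosome shares between +KTS and untagged libraries of equal number were 0.0366, −0.0713 and 0.0583, none over 0.1, and not every library correlated best with its own number. By overlap, peaks of untagged replicates 1 and 3 were most enriched over moves of 20 to 100 kb in the +KTS library of their own number (3.53 and 19.6 times). Those of untagged replicate 2 were most enriched in +KTS replicate 3 (13.2 times). For untagged replicates 2 and 3, moves alone gave 9.10% and 16.3% in +KTS replicate 2 but 1.05% and 2.31% in +KTS replicate 3. List length thus limits these ratios, and they cannot settle the pairing. Leaving out chromosome 22 from 17 to 24 Mb and a distance of 1 kb to H3K4me3, both added, changed no call among the results they were run on. Stretches of chromosomes 9 and 13 with dense untagged peaks were not left out. Moves of 20 to 100 kb, also added, kept the overlap of −KTS with +KTS regions above chance but ended the excess of +KTS replicate 3 at H3K4me3 regions found in both cells (0.770 times). No value was possible for −KTS consensus regions without a −KTS library or for H3K4me3 +KTS consensus regions without a +KTS library. Start sites, genomic features, gene lists and the motif were not run.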

Other observations

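The tests of untagged peaks in WT1 −KTS replicate 1 and of the stretch on chromosome 22 against untagged and H3K4me3 lists were chosen after their results were seen, while equal lists and other splits were planned but only afterwards used as tests of an explanation. WT1 peaks were dense on the gene-rich chromosome 19, at 3.49 and 4.03 times the genome's average in −KTS and 2.60, 2.90 and 1.88 times in +KTS. The untagged libraries stood at 0.564, 1.04 and 1.01, from only 8, 2 and 6 peaks, so these values are imprecise. H3K4me3 peaks had 3.57, 3.64 and 4.06 times the average there in −KTS and 3.92 and 3.29 in +KTS cells. The window from 27 to 28 Mb of chromosome 6, in the stretch with the main cluster of histone genes, held 193, 165 and 121 H3K4me3 peaks in −KTS cells and 95 and 120 in +KTS cells, against medians per window of 8, 11, 9, 6 and 13. Regions of H3K4me3 that held a −KTS region were wider, with a median of 1037.5 bp against 673 bp for the rest. In +KTS cells the medians were 1007 and 918 bp, or 1018.5 and 1011 bp at a score of at least 50. Wider regions meet a peak more often by chance, and no chance level was computed for these widths.

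The peaks of WT1 −KTS replicate 1 lay at H3K4me3 in 4.49% of cases and those of replicate 2 in 47.3%. A longer list alone is argued against, since the best peaks of replicate 1, as many as replicate 2 has, lay at H3K4me3 in 17.7% of cases (interval 16.4% to 19.1%). A mislabelled +KTS library is argued against from the side of replicate 2. With equal lists 25.1% of the peaks of replicate 2 lay in replicate 1 but 1.94%, 1.76% and 0.493% in the +KTS libraries. From the side of replicate 1 the gap was small, with 24.7% in −KTS replicate 2 against 20.5%, 11.2% and 5.33% in the +KTS libraries. That side was used first, and the side of replicate 2 and its bound were chosen after the shares were seen. Capture background stays open: peaks of all 3 untagged libraries lay in replicate 1 at 4.78 times or more the share after moves of 20 to 100 kb, while the list of replicate 2 is too short to compare. No biological explanation was tested, since both libraries are of 1 group.

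Peaks between 17 and 24 Mb of chromosome 22 were 9.38 times as dense as on its rest in WT1 −KTS replicate 1, 8.71 times in +KTS replicate 3, 4.45 times in −KTS replicate 2 and at most 1.77 times in +KTS replicates 1 and 2. WT1 binding as the whole cause is argued against, since 86.7% of the chromosome's peaks in untagged replicate 1 and 37 of 37 in replicate 3 lay there, and gene density is too, since H3K4me3 in −KTS cells reached at most 2.62 times, though 3.17 in H3K4me3 +KTS replicate 2. A candidate explanation is extra copies in K562, which carries a fusion of chromosomes 22 and 9. On chromosome 9, 11 of 28, 3 of 7 and 10 of 14 peaks of untagged replicates 1, 2 and 3 lay between 133 and 135 Mb. That stretch was chosen as the densest of chromosome 9 in the untagged lists. Untagged peaks also clustered outside the fused chromosomes. On chromosome 13, 50 of 66, 0 of 3 and 25 of 35 lay between 90 and 94 Mb. The edge of the chromosome 22 stretch was compared in −KTS replicate 1, +KTS replicate 3 and H3K4me3 +KTS replicate 2. By the measure set before it was computed, the steepest falls in number lay 1400 kb apart, which spoke against extra copies. In −KTS replicate 1, however, that measure met a gap inside the stretch, at 22.3 Mb. As a ratio, chosen after that, the largest fall lay at 23.7, 23.7 and 23.6 Mb, so copy number stays open, and read coverage of the inputs, which would decide, was not analysed here.

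The 24103 regions found in H3K4me3 +KTS replicate 2 alone (4296 with equal lists) overlapped the capture peaks of WT1 +KTS replicate 3, whose list carries the same code in its name, at 14.5 times the share after moves of 20 to 100 kb (16.6% against 1.15%). They lay in +KTS replicates 1 and 2, which carry other codes, in 86.8% and 66.3% of cases, or 4.20 and 4.88 times, and in −KTS replicate 1 in 33.6%, or 7.52 times, so the overlap was not particular to +KTS. Regions found in all 5 H3K4me3 libraries overlapped +KTS replicate 3 at 0.448 times (1.92% against 4.30%). A background common to both kinds of library would give a share above this level. The level is low in itself, since +KTS replicate 3 lay under local moves at H3K4me3 regions found in both cells (0.770 times). Passing it therefore cannot decide for a common background. The ratio in +KTS replicate 3 was 14.9 for regions of H3K4me3 +KTS replicate 1 alone and 12.5, 1.87 and 0.110 for those of −KTS replicates 3, 1 and 2 alone. Regions of H3K4me3 +KTS replicate 1 alone lay in WT1 +KTS replicate 2, whose list carries their code, in 74.1% of cases, or 4.54 times. In WT1 +KTS replicates 1 and 3 these were 55.2% and 15.9%, or 2.43 and 14.9 times. Local moves alone gave 16.3% in WT1 +KTS replicate 2 and 1.07% in replicate 3, so list length limits the ratio. These ratios therefore cannot show whether a shared code matters. A common background may account for part of these regions and stays open, and binding of +KTS at weak H3K4me3 regions stays open as untested.

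Of the 10 ways to split the 5 H3K4me3 libraries into 3 and 2, 3 gave at least 1710 regions in all libraries of one side and none of the other, and these 3 include the split by isoform, which gave 1710. The others gave 1951 and 2104. With 10 splits no share under 0.05 can be reached.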
